A study of Mus musculus with 4 samples.

How the data were processed

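The data are RNA-seq gene counts from regenerating mouse digit tips collected 14 days after amputation. There were 4 groups with 1 library each, namely wildtype, Sp6 conditional knockout (cKO), Sp8 cKO and Sp6+Sp8 cKO. The 3 cKO libraries carried batch 1 in the labels and the wildtype library batch 3, so batch and knockout status cannot be told apart in any comparison with wildtype, while comparisons among the cKO libraries lie within batch 1. Per the labels' protocols, knockout was induced with tamoxifen at 75 mg/kg, given daily over 5 days and ended 5 days ahead of amputation. The labels' protocols describe amputations of the distal and of the middle phalanx without saying which applies to these samples, and the label of digit tip regenerates was taken to mean the distal phalanx. Whether the wildtype mice received tamoxifen, the Cre driver, the strain, the sex and the number of digits or animals per library are not given in the sources used here.

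Per the labels' protocols, tissue proximal to the distal interphalangeal joint was trimmed away, poly-A RNA was made into strand-specific (dUTP) libraries, and paired-end reads of 150 bp were sequenced on a DNBSEQ-T7 instrument and filtered for quality. The submitters' processing notes name Trim Galore 0.6.4, STAR, featureCounts, edgeR, deepTools and Salmon, without their roles or settings, and genome build GRCm38. The annotation release is not given in the sources used here. The deposited values are estimated counts per gene, as Salmon gives, not scaled for depth, for 45706 genes. In each column between 84.6% and 87.1% of the values were whole numbers. Estimated counts depend on how reads shared by near-identical genes were divided, so genes with close copies or processed pseudogenes are uncertain. The table held 1 further column that matches no listed sample and was not used.

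Estimated counts were rounded to whole numbers. Library scaling used TMM factors of edgeR 4.0.16 in R 4.3.3 over the 4 libraries, and log2 ratios were taken from log2 CPM with a prior count of 2. Gene positions and types came from GENCODE M21, on GRCm38, by gene identifier, and 98.8% of identifiers were found there. Where several identifiers carried 1 symbol, gene lists used the identifier with the highest mean CPM.

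With 1 library per group there is no replicate check, no difference was tested and no p-value is given. Each comparison describes 2 libraries, not 2 conditions. Genes were instead counted by a size rule, fixed before the data were examined along with the gene lists, the rule for named genes and the settings to be varied. A gene was past the size rule with a log2 ratio of at least 1 in either direction, a CPM of at least 1 in at least 1 of the 2 libraries, and an exact Clopper-Pearson 95% interval of the ratio, conditional on the sum of both counts, that excluded 1. Intervals cover counting error only. They may be too narrow even for that, since reads amplified by PCR without molecular identifiers are not independent molecules. The fold against a library with 0 counts was computed against 3 counts and is a lower bound. Each of 39 gene lists was described by its members with a CPM of at least 1 in at least 1 of the 4 libraries, the number past the size rule, its median log2 ratio and the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. These percentiles describe the libraries and are not p-values.

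The genes named were Sp6 and Sp8, then for each comparison the 10 highest and 10 lowest log2 ratios among genes past the size rule with a CPM of at least 10 in the higher library, up to 4 members of each list per comparison by absolute log2 ratio, and genes that shared a direction in the 3 cKO libraries. Predicted genes, immunoglobulin and T cell receptor segments and sex-linked genes were left out of the top genes. That ranking was filled largely by small nuclear and nucleolar RNAs, histone genes and processed pseudogenes, so a ranking of protein-coding genes without histones was added after seeing the data. The glucocorticoid-responsive and inner root sheath genes, the keratin-associated protein, Skint, Sprr2 and Serpinb3 families, the neighbours of Sp6, and the other genes named outside the lists were also chosen after their values were seen. The 8 clock genes of the time of day test were chosen after Per2 was seen but before their own values were, and the other circadian genes were added later.

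The procedure was tested on simulated data with known fold changes. For Sp6 cKO against wildtype, with counting error only, it recovered 50 of 50 genes changed 4-fold, 44 changed 2.5-fold and 1 changed 1.5-fold, and put 31 of 16169 unchanged genes past the size rule. With an assumed biological coefficient of variation of 0.2 it recovered 49, 37 and 3 of these and put 508 of the unchanged genes past the rule. The alternatives tried were size factors of DESeq2 1.42.0, library totals alone, library totals without the 20 most abundant genes, no low-count filter, a CPM of at least 5, prior counts of 0.5 and 5, no interval requirement, a gene set without predicted genes and, added after seeing the data, protein-coding genes without histones. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for all other steps.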

Results

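The mouse digit tip regrows after amputation through the distal phalanx, under a regenerating nail epidermis, and the samples were taken to come from such amputations. The series concerns gene delivery for digit regeneration built on conserved epidermal factors, and these libraries ask how digit tips differ when Sp6, Sp8 or both, a pair of related zinc-finger transcription factors of the epidermis, are conditionally deleted. Gene counts were measured in whole digit tip regenerates 14 days after amputation, with 1 library for each of the 4 genotypes. Counts summed to 21834883 in wildtype, 13054843 in Sp6 cKO, 12588511 in Sp8 cKO and 15146015 in Sp6+Sp8 cKO, and 17332 genes reached a CPM of 1 in at least 1 library. There were no replicates, so no difference below has been tested against variation between animals, and the intervals given cover counting error only.

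The targeted genes were examined first. Sp6 (ENSMUSG00000038560, GRCm38 chromosome 11, 97013394 to 97024734) stood at 97.7 CPM in wildtype and 29.2 CPM in Sp6 cKO, which is 3.34-fold lower (95% interval 3.00 to 3.74). It was 95.6 CPM in Sp8 cKO, with a log2 ratio to wildtype of -0.03. In Sp6+Sp8 cKO, Sp6 was 57.8 CPM, 1.69-fold lower (95% interval 1.56 to 1.83), and this log2 ratio of -0.76 did not reach the size rule. Sp8 (ENSMUSG00000048562, chromosome 12, 118846329 to 118852576) stood at 63.9 CPM in wildtype and 66.1 CPM in Sp6 cKO. It was 3.82-fold lower in Sp8 cKO, a log2 ratio of -1.92, and 4.78-fold lower (95% interval 4.12 to 5.55) in Sp6+Sp8 cKO. The counts cover whole genes, so transcripts that lack only a deleted exon would still be counted. The Sp6+Sp8 cKO library therefore carried a clear shortfall of Sp8 transcripts and only a partial shortfall of Sp6 transcripts.

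**Figure D1:**
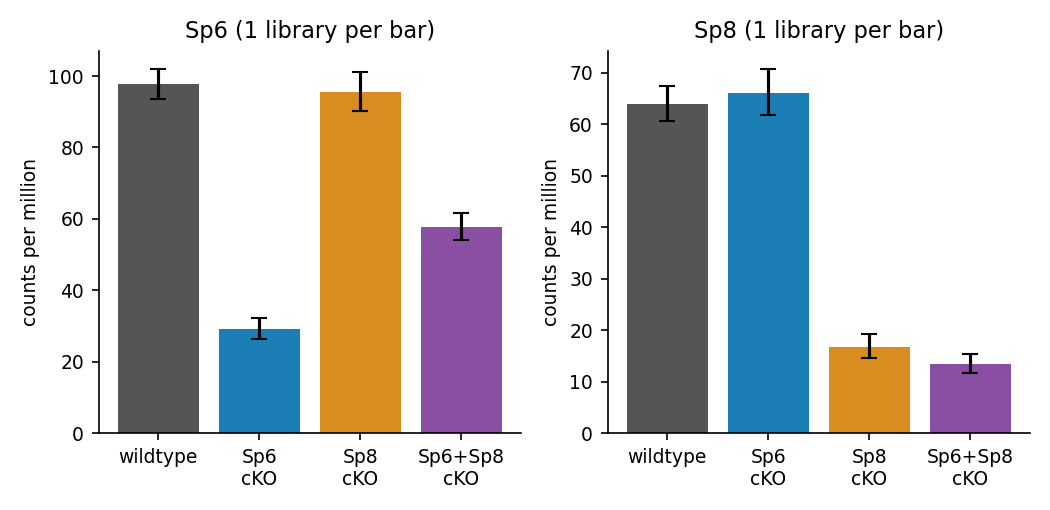
Sp6 (left) and Sp8 (right) in CPM on the vertical axis, with 1 bar per library and exact Poisson 95% intervals as error bars. Sp6 was 29.2 in Sp6 cKO and 57.8 in Sp6+Sp8 cKO against 97.7 in wildtype, and Sp8 was 16.8 in Sp8 cKO and 13.4 in Sp6+Sp8 cKO against 63.9 in wildtype.

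The Sp6 cKO library differed from wildtype in some nail and hair keratin genes, which were lower, and in some wound-keratinocyte, chemokine and T cell genes, which were higher. In the nail and hair keratin list 6 of 23 measured members were lower past the size rule and none was higher, with a median log2 ratio of -0.18 (percentile 0 of matched random lists). Krt82, a hair cuticle keratin, was 5.55-fold lower (95% interval 4.50 to 6.93). Krt32, Vsig8, Crnn, Tchh (trichohyalin) and S100a3 had log2 ratios of -1.84, -1.74, -1.32, -1.17 and -1.01. The inner root sheath keratins Krt72 and Krt26 were at -2.62 and -2.14, Tchhl1 at -2.23 and Lyg2, a lysozyme, at -2.60. Of 55 measured keratin-associated protein genes, which encode matrix proteins of hair and nail, 15 were lower and 1 was higher, although the family median was 0.17 and the log2 ratio of the family sums 0.36. Krtap28-13, Krtap24-1 and Krtap5-4 were among the lowest of them, at -3.20, -2.96 and -2.89. The abundant cortical keratins Krt33b, Krt34, Krt81 and Krt86 stayed within the size rule, at -0.16, 0.35, 0.09 and 0.26.

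In the same library 12 of 28 wound-activated keratinocyte genes were higher than in wildtype and 1 was lower (median 0.57, percentile 100). S100a8, a subunit of calprotectin, was 5.69-fold higher (95% interval 4.84 to 6.72), and S100a9, Sprr2d, Lce3b and Lce3e had log2 ratios of 2.57, 1.59, 3.14 and 2.66. Lcn2, an iron-scavenging protein of inflamed epithelium, was at 2.09 and Zc3h12a, a ribonuclease that degrades inflammatory transcripts, at 1.97. Among inflammatory cytokines 6 of 13 were higher and none was lower, with the neutrophil chemoattractants Cxcl5, Cxcl2 and Cxcl1 at 3.36, 2.73 and 2.69. Il17a had 15 counts against 0 in wildtype, at least 8.43-fold higher. Of the T cell and innate lymphoid genes 4 of 8 were higher and none lower (median 1.33, percentile 100), led by Trdc, the delta T cell receptor constant gene, which was 9.93-fold higher (95% interval 5.99 to 17.4). Cd3e, Cd3g and Il2rb were at 2.62, 2.31 and 2.25. The other immune lists went different ways. Mast cell genes had a median of 0.78 and macrophage and monocyte genes of 0.48 (percentile 100 for each), with 2 of 8 and 2 of 15 members higher. Langerhans and dendritic cell genes had a median of -0.19 (percentile 2.34), and interferon response genes of -0.14. In the neutrophil list, which holds S100a8 and S100a9, 4 of 13 members were higher and none lower although the median was -0.06. In the osteoclast list, with a median of 0.35, 1 of 14 members passed the rule. Melanocyte genes were higher for 4 of 6 members, with Tyr and Dct at 1.69 and 1.55, from 8 and 27 counts in wildtype. The basal keratinocyte list had no member past the size rule and a median of -0.26 (percentile 0).

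Across all genes 379 were higher and 364 lower in Sp6 cKO than in wildtype, of 16884 compared. Among protein-coding genes without histones, the highest log2 ratios belonged to Slc15a2 (3.99), a peptide transporter, Scrn2 (3.63), Skint9 (2.83), S100a8, Xaf1 (2.30), Skint3 (2.30), Skint4 (2.13), Lcn2, Chil1 (2.08) and Ccl8 (2.05). The lowest belonged to Cwc22 (-3.31), a splicing factor whose copy number varies between mouse strains, followed by keratin-associated and hair genes and Spon2 (-2.42). The count of lower genes was 218 without predicted genes. The fixed ranking over all gene types was led by Hist2h3c1, Rnu3b1 and Rnu3b3, all at 0 counts in wildtype, and by the pseudogene Rpsa-ps10 (-6.80), and these multicopy features are uncertain because their reads are shared with near-identical copies.

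The Sp8 cKO library differed from wildtype in some osteoclast, mast cell, globin, cytokine and wound-keratinocyte genes, which were higher. No nail and hair keratin gene of 23 measured passed the size rule in either direction, and the median log2 ratio was 0.02. Of the keratin-associated protein genes 7 were higher and 0 lower, among them Krtap20-2 at 2.03 and Krtap9-3 at 1.44, and the family median was 0.38 and the log2 ratio of the family sums 0.47. In the osteoclast list 4 of 14 members were higher (median 0.69, percentile 100). Mmp9, a matrix metalloproteinase, was 5.19-fold higher (95% interval 4.74 to 5.67), and Ctsk (cathepsin K), a collagen-degrading protease, and Oscar were at 1.32 and 1.76. Ibsp, bone sialoprotein, was at 1.19 and was the 1 osteoblast gene of 19 past the rule. Mast cell genes were higher for 5 of 8 members (median 1.06, percentile 100), with the proteases Mcpt4, Tpsab1 and Cpa3 at 1.41, 1.14 and 1.10. Globin genes Hba-a2 and Hbb-bs were at 1.91 and 1.51, and 4 of 7 erythroid genes were higher, so the content of blood RNA differed between these libraries.

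Wound-activated keratinocyte genes were higher in Sp8 cKO for 6 of 28 members and lower for none (median 0.17, percentile 99.9). Basal and suprabasal keratinocyte genes had medians of -0.21 and -0.15 (percentile 0 for each) with no member past the rule. Macrophage and monocyte genes had a median of 0.55 (percentile 100), with 1 member higher and 1 lower. Among cytokines 5 of 13 were higher, with Cxcl5 at 3.32 and Il1b at 1.40. S100a8, Skint4 and Ccl8 were at 1.78, 2.31 and 2.22. Of the neutrophil list 3 of 13 members were higher and 1 was lower. T cell genes were higher for 2 of 8 members (median 0.67, percentile 99.94), where Trdc was 3.36-fold higher (95% interval 1.85 to 6.29) and Cd3e, at 0.88, did not pass the rule. The interferon response list had a median of 0.70 (percentile 99.98) and 1 of 13 members past the rule, Isg15 at 1.90 from 13 counts. Gvin1, an interferon-inducible GTPase, had 130 counts in this library and 0 in the 3 others, at least 74.8-fold higher. All-or-none counts were also seen for multicopy features, and whether Gvin1 shares reads with near-identical copies was not examined. The lowest protein-coding genes were Cwc22 (-3.06), Spon2 (-2.84), Adh6a (-2.48), Sp8 (-1.92), Serpina3a (-1.67), Cyp17a1 (-1.64), H2-Eb1 (-1.44) and Reep1 (-1.35). Of 16878 genes 383 were higher and 262 lower, and the latter count was 145 without predicted genes. Xist, expressed from the inactive X chromosome, stood at 27.9 CPM in Sp8 cKO against 1526 CPM in wildtype, while Y-linked Kdm5d was 65.3 and 43.2 CPM, so the sex makeup of these libraries differed.

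The Sp6+Sp8 cKO library had the most genes past the size rule against wildtype, 479 higher and 497 lower of 16861, or 508 and 474 with library totals as the scaling. The medians of the nail and hair, cornified keratinocyte, chondrocyte, tendon and osteocyte lists were below those of matched random lists, with few members past the size rule, while some cytokine, T cell, osteoclast and immediate early genes were higher. In the nail and hair keratin list 6 of 23 members were lower and 1, Dsc2, was higher (median -0.81, percentile 0). Crnn, Krt33b, Vsig8, Dsg4, Krt83 and Krt82 were at -1.73, -1.26, -1.14, -1.14, -1.13 and -1.13. The abundant keratins Krt34, Krt81 and Krt86 were at -0.98, -0.96 and -0.88, just inside the rule. Of 55 keratin-associated protein genes 14 were lower and 0 higher, with Krtap1-5 at -1.96. The suprabasal and cornified list had 3 of 32 members lower and a median of -0.55 (percentile 0), with Lce1m, Krt77 and Krtdap at -1.88, -1.43 and -1.06. Krtdap was 2.08-fold lower (95% interval 2.01 to 2.16).

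In the skeletal and connective tissue lists of this library, Chad (chondroadherin) was 2.55-fold lower (95% interval 2.34 to 2.79) and Col2a1 was at -1.34, with 2 of 10 chondrocyte genes lower (median -0.39, or -0.18 among members with a CPM of at least 5). The bone matrix genes Bglap and Bglap2 were at -1.56 and -1.09, and Ibsp was higher at 1.01. The osteocyte genes Sost (sclerostin) and Dkk1 were at -1.25 and -1.08. Tendon genes had a median of -0.49, endothelial genes of -0.31 and fibroblast genes of -0.19, with 1 of 10, 0 of 14 and 0 of 20 members lower. Mest and Mdk, from the blastema list, were at -1.11 and -1.09, and that list's median was -0.04. Osteoclast genes were higher for 5 of 14 members (median 0.75, percentile 100), with Mmp9, Oscar, Ocstamp and Atp6v0d2 at 2.44, 2.32, 1.86 and 1.77.

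Cytokine genes in Sp6+Sp8 cKO were higher for 5 of 13 members (median 1.45, percentile 100), with Cxcl5, Cxcl2 and Ptgs2 at 3.87, 2.95 and 1.76. S100a9 was 10.1-fold higher (95% interval 7.03 to 15.1), and Trdc was 9.03-fold higher (95% interval 5.47 to 15.8), with 4 of 8 T cell genes higher. Of the neutrophil list 4 of 13 members were higher and 2 lower, with a median of -0.29. The wound-activated list had 7 of 28 members higher and 1, Sprr1b at -1.23, lower. Its median of 0.19 became -0.07 among members with a CPM of at least 5. The immediate early genes Fosb, Atf3, Fosl1 and Nr4a1 were at 2.97, 2.92, 1.39 and 1.24, while Fos was at -0.84. In the technical list of immediate early and handling stress genes 4 of 18 members were higher, 0 were lower and the median was 0.16. Mitochondrially encoded genes took 6.24% of the counts against 4.73% in wildtype, with a list median of 0.29. Scrn2 (16.8-fold higher), Per2 (3.08) and Serpinb3d (2.70) were among the highest protein-coding genes. H2-Eb1, a class II major histocompatibility gene, was 23.8-fold lower (95% interval 14.9 to 40.5). In the Langerhans and dendritic cell list 1 of 9 members was lower, 0 were higher and the median was 0.03. Cwc22 (-3.96), Spon2 (-3.32), Scd3 (-2.38), Lyg1 (-2.12), Tmprss11c (-2.10) and Cyp4f13 (-2.05) were also among the lowest protein-coding genes.

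**Figure D2:**
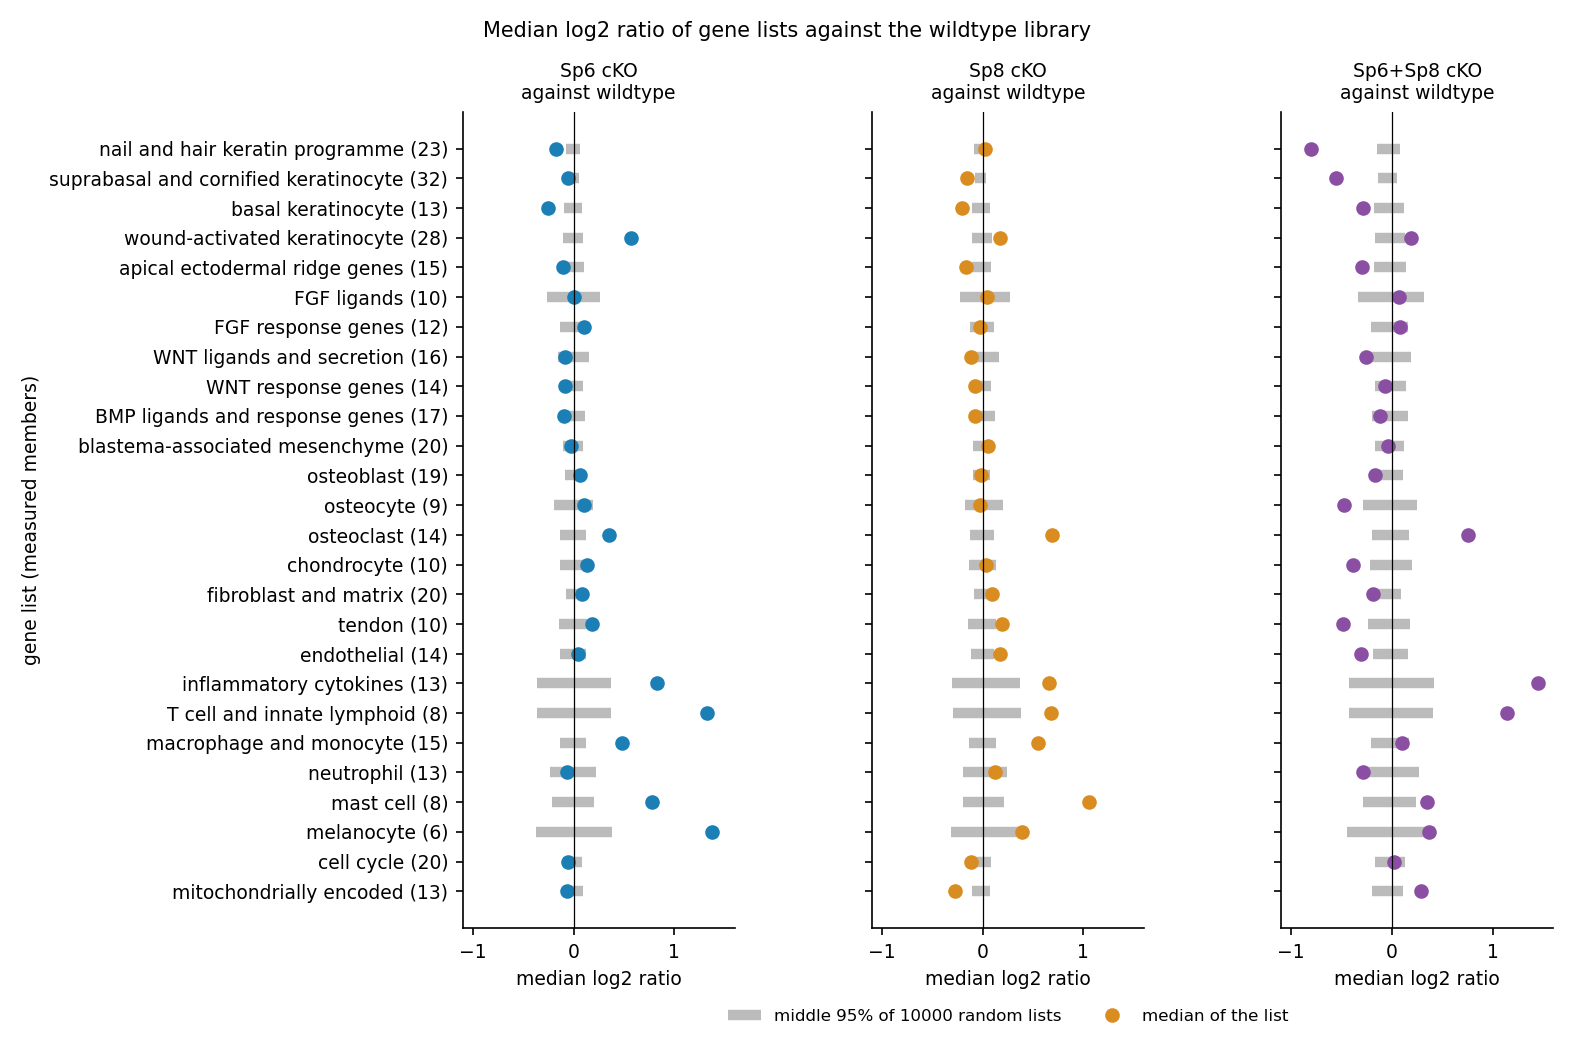
Median log2 ratio to the wildtype library (horizontal axis) of gene lists fixed before the data were examined (vertical axis, measured members in parentheses), with 1 panel per cKO library. Points are list medians and grey bars hold the middle 95% of 10000 random lists matched on expression. The nail and hair list lies at -0.18, 0.02 and -0.81, and the osteoclast list at 0.35, 0.69 and 0.75.

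Few members of the signalling lists passed the size rule. Fgf8, the ridge signal of the limb bud, had counts of 0 in wildtype, Sp6 cKO and Sp6+Sp8 cKO and 1 in Sp8 cKO, so it was not detectable at this depth, where 3 counts correspond to between 0.138 and 0.238 CPM. Of 10 measured FGF ligands only Fgf18 passed the size rule against wildtype, at -1.52 in Sp8 cKO and -1.74 in Sp6+Sp8 cKO, from 30 counts in wildtype and 5 in each of these libraries. No FGF response gene of 12, no WNT response gene of 14 and no BMP ligand or response gene of 17 passed the rule in any of the 6 comparisons. Wnt3a was lower in the 3 cKO libraries, at -1.86, -1.24 and -1.19, and Wnt5b was at -1.43 in Sp6+Sp8 cKO, where 2 of 16 WNT ligand genes were lower and the list median was -0.26 (percentile 1.36). The apical ectodermal ridge list had medians of -0.11, -0.17 and -0.30 in Sp6 cKO, Sp8 cKO and Sp6+Sp8 cKO (percentiles 2.18, 0.07 and 0.05), with only Sp6 or Sp8 themselves past the rule. No cell cycle gene of 20 passed the rule in any comparison, and the list median in Sp8 cKO was -0.12 (percentile 0.93).

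Genes that differed in the same direction from wildtype in the 3 cKO libraries numbered 89 higher and 89 lower. Independent lists of these sizes would share 0.231 and 0.158 genes. Unchanged libraries simulated against 1 common control shared 0 in either direction with counting error only. At an assumed biological coefficient of variation of 0.2 they shared 19.5 higher and 5.5 lower genes, and at 0.25 they shared 66.5 and 26.5. The wildtype library cannot be split, so part of the excess may come from the shared control. Sp8 cKO shared 144 higher genes with Sp6 cKO and 145 with Sp6+Sp8 cKO, against 49.5 and 52.5 simulated at 0.2. These counts were no more than the 153.5 and 150.5 simulated at 0.25. Sp6 cKO and Sp6+Sp8 cKO shared 184, against 52 at 0.2 and 150 at 0.25. The same pairs shared 123, 139 and 181 lower genes. The simulated values were 25.5, 26.5 and 28 at 0.2 and 91.5, 92 and 93 at 0.25. At 0.25 the simulated lists of higher genes were longer than the observed ones, at 571, 578.5 and 564.5 against 379, 383 and 479. Overlaps simulated at 0.25 may therefore be too high. The highest were the multicopy features Hist2h3c1, Rnu3b1, Rnu3b3 and Rnu1b2, at 0 counts in wildtype. The lowest were mostly processed pseudogenes and small RNAs, among them Rpsa-ps10, Rnu1b1, Rps2-ps13 and Rps24-ps3. All of these are uncertain because of shared reads. The ribozyme RNA Rpph1 was also higher, at 517, 1113 and 675 CPM in Sp6 cKO, Sp8 cKO and Sp6+Sp8 cKO against 97.0 in wildtype. The source of its difference was not tested. Among protein-coding genes, Cxcl5 was at 3.36, 3.32 and 3.87 in Sp6 cKO, Sp8 cKO and Sp6+Sp8 cKO. Cxcl13, a B cell chemoattractant, was at 3.92, 3.51 and 4.96, and S100a9 at 2.57, 2.13 and 3.24. Wildtype stood at only 0.322 CPM for Cxcl5, 0.184 for Cxcl13 and 1.52 for S100a9, and the 3 ratios of each gene share that value. The period gene Per2 was higher in each, at 1.92, 2.02 and 3.08, and the clock activators Arntl and Npas2 were at -1.24 and -1.58 in Sp6+Sp8 cKO. The collection time of the tissue is not given in the labels. The imprinted RNA H19 was at -1.47, -1.55 and -1.55. Within batch 1, Per2 was also higher in Sp6+Sp8 cKO than in Sp6 cKO and Sp8 cKO, at 1.16 and 1.06. The comparisons with wildtype set batch 1 against batch 3, and no within-batch value exists for them because the only wildtype library was in batch 3.

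**Figure D3:**
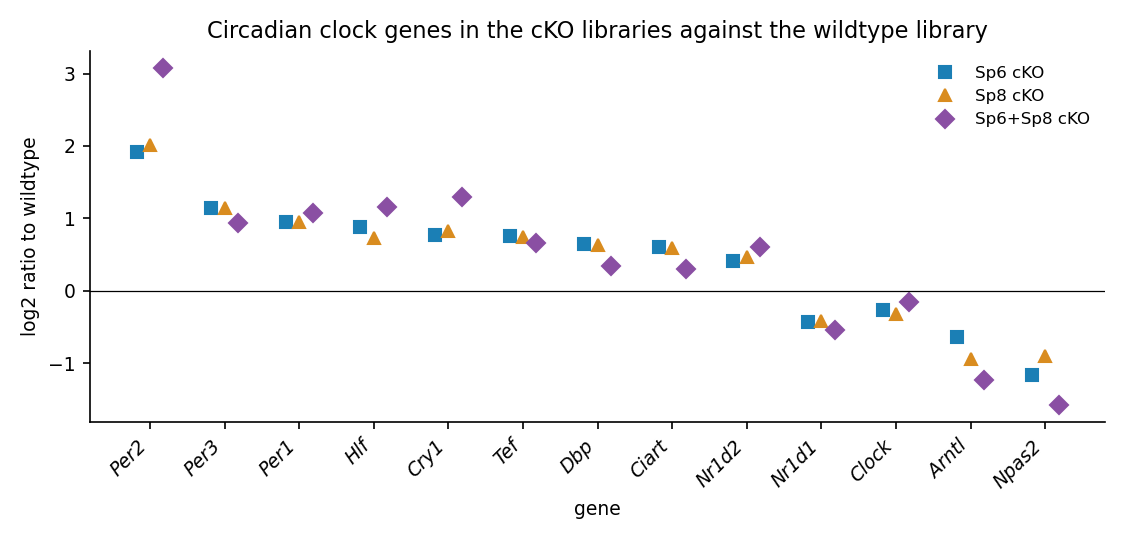
Log2 ratio to the wildtype library (vertical axis) of circadian clock genes (horizontal axis), with 1 symbol per cKO library. Per2 lies at 1.92, 2.02 and 3.08 and Npas2 at -1.17, -0.91 and -1.58.

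Within batch 1, the Sp8 cKO library had 296 genes higher and 229 lower than the Sp6 cKO library, of 16912. Some hair and nail genes were higher in Sp8 cKO and some wound-keratinocyte and T cell genes lower. Of the keratin-associated protein genes 18 were higher and 0 lower, although the family median was 0.47 and the log2 ratio of the family sums 0.11. Krtap28-13, Krtap24-1, Krtap5-4 and Krtap12-1 were at 3.46, 2.94, 2.77 and 2.39. Krt72 was 7.02-fold higher (95% interval 5.31 to 9.44) and Krt26 and Lyg2 were at 2.61 and 2.42. In the nail and hair list 4 of 23 members were higher, Krt82 (2.35), Vsig8 (1.76), Krt32 (1.68) and S100a3 (1.19), and the median was 0.27 (percentile 100). Wound-activated keratinocyte genes were lower for 7 of 28 members and higher for 1 (median -0.42). Sprr2i, Sprr2b, Sprr2d and Serpinb3d were at -1.93, -1.81, -1.74 and -1.46. Zc3h12a was 3.74-fold lower (95% interval 3.25 to 4.32), and Alox8, a lipoxygenase, and Lcn2 were at -1.57 and -1.46. T cell genes were lower for 4 of 8 members, with Il2rb and Cd3e at -1.79 and -1.74. Oscar, an osteoclast receptor, was higher at 1.31. Scrn2, which lies within 1 Mb of Sp6, was lower at -2.93, and 4 of the 47 other expressed genes in that window passed the size rule against 513 of 16777 elsewhere. Interferon response genes were higher for 4 of 13 members, including Oasl2 at 1.39. Xist was at 1963 CPM in Sp6 cKO, so sex makeup differed here too. Erythroid genes had a median of 0.69 (percentile 100), with 1 of 7 members higher. Immediate early and handling stress genes had a median of -0.15 and mitochondrially encoded genes of -0.12 (percentiles 0.02 and 0.28).

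Adding the Sp8 label to the Sp6 label, Sp6+Sp8 cKO against Sp6 cKO gave 318 genes higher and 351 lower of 16848, a balance that turned to 348 and 302 with library totals as the scaling. Sp6 itself was 1.98-fold higher (95% interval 1.75 to 2.24) in Sp6+Sp8 cKO, just within the size rule. The immediate early genes Fosb, Atf3, Fosl1 and Nr4a1 were higher at 2.06, 1.92, 1.55 and 1.44, while Fos was lower at -1.19. In the immediate early and handling stress list 4 of 18 members were higher, 1 was lower and the median was 0.06. Keratin-associated protein genes went both ways, 9 higher and 18 lower. Krtap24-1, Krtap28-10, Krtap5-5 and Krtap16-1 were at 1.76, 1.52, 1.35 and 1.33, and Krtap1-5, Krtap9-3 and Krtap6-5 at -2.58, -2.14 and -1.91. The keratins followed the same division, with Krt82 and Krt32 at 1.32 and 1.03 and Krt34, Krt86, Krt33b and Krt81 at -1.32, -1.14, -1.11 and -1.05. Wound-activated keratinocyte genes were lower for 7 of 28 members and higher for 1 (median -0.62), with Lce3c at -2.12, and Skint9 was at -2.03. Lists of many cell types had medians below those of random lists, among them tendon (-0.55), chondrocyte (-0.48, with Chad at -1.39), suprabasal keratinocyte (-0.48), endothelial (-0.33), macrophage (-0.33), osteoblast (-0.31) and fibroblast (-0.27), with no osteoblast or fibroblast gene past the rule. Mitochondrially encoded genes had a median of 0.39, with 13 of 13 above 0. H2-Eb1 was at -3.16, and Tmprss11c and Degs2 were at -2.20 and -1.85. Oscar and Atp6v0d2 were higher at 1.87 and 1.19. The count of higher genes was 157 without predicted genes.

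Adding the Sp6 label to the Sp8 label, Sp6+Sp8 cKO against Sp8 cKO gave 317 genes higher and 473 lower of 16889, the largest total of the 3 within-batch comparisons. Of the keratin-associated protein genes 30 were lower and 0 higher, with Krtap9-3, Krtap1-5, Krtap16-3 and Krtap6-5 at -3.17, -2.57, -2.38 and -2.07. In the nail and hair list 9 of 23 members were lower (median -0.64, percentile 0). Krt34 was 2.55-fold lower (95% interval 2.47 to 2.64), and Krt33b, Krt86, Krt81 and Vsig8 were at -1.34, -1.29, -1.17 and -1.16. Krt26, Tchhl1 and Krt72 were at -2.09, -2.04 and -1.93. Scrn2 was 10.1-fold higher (95% interval 7.57 to 13.9), and Fosb, Atf3, Serpinb3d, Sprr2i, Zc3h12a and Sprr2b were at 3.18, 2.41, 2.24, 1.96, 1.93 and 1.77. T cell genes were higher for 4 of 8 members, with Cd3g and Trdc at 1.72 and 1.39. Macrophage genes had a median of -0.44, mast cell genes of -0.71 and tendon genes of -0.66, each below the middle range of random lists. Mitochondrially encoded genes had a median of 0.54. The count of higher genes was 180 without predicted genes, and Xist was at 3528 CPM in Sp6+Sp8 cKO.

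**Figure D4:**
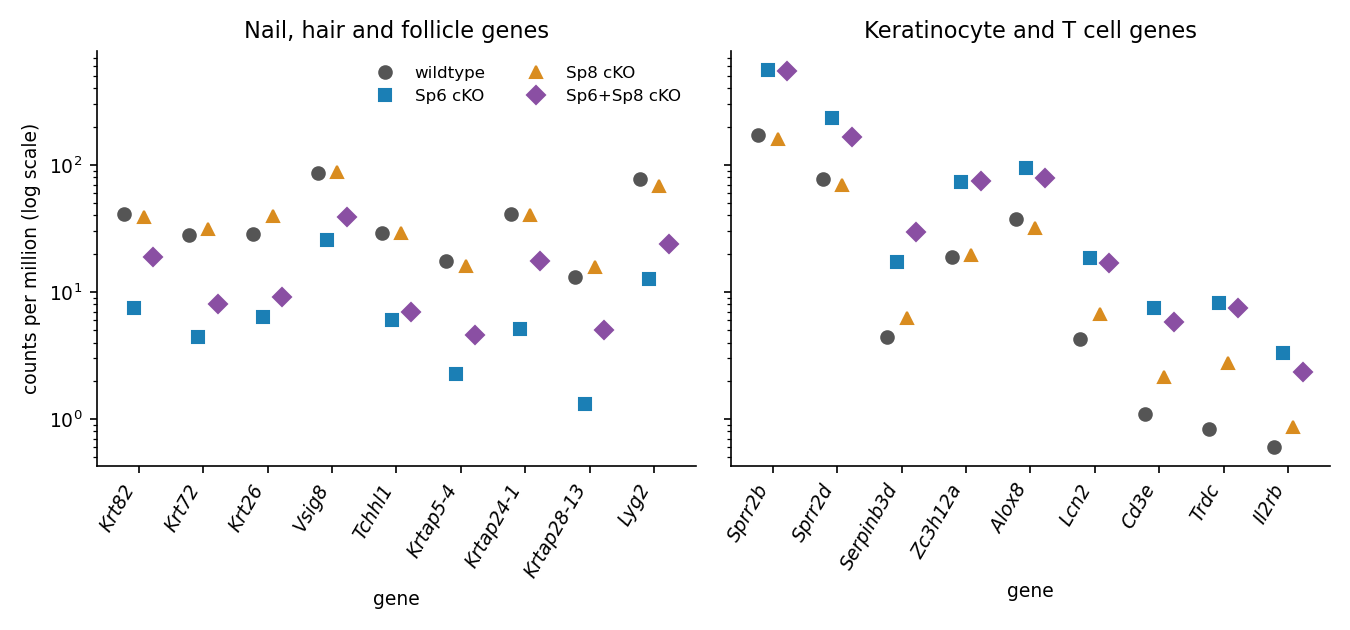
CPM on a log scale (vertical axis) of nail, hair and follicle genes (left) and keratinocyte and T cell genes (right), with 1 symbol per library. In Sp6 cKO and Sp6+Sp8 cKO, Krt72 was at 4.42 and 8.06 CPM and Zc3h12a at 73.6 and 75.2 CPM, against 27.9 and 31.0 and against 18.7 and 19.7 CPM in wildtype and Sp8 cKO.

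Across genes, Pearson's r of log2 CPM lay between 0.966, for Sp6+Sp8 cKO with wildtype, and 0.980, for Sp8 cKO with Sp6 cKO, and genes are not independent replicates. The counts past the size rule are of the size that unreplicated variation can give. With no change at all, simulated Sp6 cKO and wildtype libraries had 245.5 higher and 268.0 lower genes at an assumed biological coefficient of variation of 0.2, and 571.0 and 608.5 at 0.25, against the 379 and 364 observed. Single genes named above therefore carry an unknown error between animals.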

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

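The contrasts below were examined after the list and gene values had been seen, and none of the differences was tested, because each rests on 4 libraries with 1 per genotype. A list was singled out when its median log2 ratio for loss of 1 gene lay outside the middle 95% of matched random lists in opposite directions with the other gene intact and with it also deleted. Each value is the second median minus the first. For a single gene, the contrast for loss of Sp6 is the same quantity as that for loss of Sp8, so the values of a list for both are not independent of each other. Comparisons with the other gene intact set batch 1 against batch 3. Sp6 transcripts were only partly lower in the Sp6+Sp8 cKO library, at 57.8 CPM against 29.2 CPM in Sp6 cKO.

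For loss of Sp8, wound-activated keratinocyte genes differed by -0.80, from 0.17 with Sp6 intact to -0.62 with Sp6 also deleted. Mast cell genes differed by -1.56, macrophage and monocyte genes by -0.87, melanocyte genes by -0.83, tendon genes by -0.74, endothelial genes by -0.50 and fibroblast and matrix genes by -0.36. Mitochondrially encoded genes differed the other way, by 0.67, from -0.28 to 0.39. For loss of Sp6, mast cell genes differed by -1.49, from 0.78 with Sp8 intact to -0.71 with Sp8 also deleted. Macrophage and monocyte genes differed by -0.92, erythroid genes by -0.88, tendon genes by -0.84 and fibroblast and matrix genes by -0.39.

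Single genes were singled out when they passed the size rule in opposite directions in the same way, and sex-linked lists and Xist were left out of those named. Over all genes there were 56 for loss of Sp8, of which 40 were higher with Sp6 intact and lower with Sp6 also deleted, and 59 for loss of Sp6, of which 39 were higher and then lower. Among named genes, the log2 ratio of Sp6+Sp8 cKO to Sp6 cKO minus that of Sp8 cKO to wildtype was -3.16 for Skint3, -3.74 for Skint4 and -4.34 for Skint9, members of a family expressed in skin keratinocytes. It was -4.44 for Lce3b, -2.61 for Lce3c and -3.14 for Lce3e, late cornified envelope genes, and -3.80 for Krtap20-2, -3.03 for Krtap6-5 and -3.58 for Krtap9-3, which encode hair matrix proteins. Stfa1 differed by -5.99, a value that depends on the prior count because wildtype had no counts, with 0, 28, 33 and 10 counts in wildtype, Sp6 cKO, Sp8 cKO and Sp6+Sp8 cKO. The peptide transporter Slc15a2 differed by -3.33, the Fc receptor Fcgr1 by -4.15, the mast cell protease Mcpt4 by -2.45 and the bone matrix gene Mepe by -2.67. Flg differed by -4.07, for an identifier other than the one used in the gene lists, since several identifiers share this symbol. The histone genes Hist1h4m and Hist1h2ab differed by -8.79 and -5.73, and they have near-identical copies that share reads, with 3 and 12 counts in wildtype.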

How the results depend on the processing

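The gene set of protein-coding genes without histones and the prior count of 5 for each named gene were chosen after the data had been seen, and all other settings before. Of 120 recomputed counts of genes past the size rule, 95 stayed within 1.5 times the value reported and 25 did not. A CPM of at least 5 left 118 higher and 137 lower genes for Sp6 cKO against wildtype, 110 and 82 for Sp8 cKO, and 164 and 212 for Sp6+Sp8 cKO. It left 85 and 129 for Sp6+Sp8 cKO against Sp6 cKO, 97 and 180 against Sp8 cKO, and 80 and 55 for Sp8 cKO against Sp6 cKO. Fewer genes are compared at this minimum. Without any low-count filter Sp8 cKO against wildtype had 591 higher genes.

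Without predicted genes, lower genes numbered 218 for Sp6 cKO and 145 for Sp8 cKO against wildtype, and higher genes 157 for Sp6+Sp8 cKO against Sp6 cKO, 180 against Sp8 cKO and 184 for Sp8 cKO against Sp6 cKO. Among protein-coding genes without histones, lower genes numbered 214 for Sp6 cKO and 113 for Sp8 cKO against wildtype. Sp6+Sp8 cKO had 298 higher and 321 lower genes. Higher genes numbered 149 for Sp6+Sp8 cKO against Sp6 cKO and 153 against Sp8 cKO, and 144 genes were lower for Sp8 cKO against Sp6 cKO. These gene sets are smaller than the full table.

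The median of wound-activated keratinocyte genes in Sp6+Sp8 cKO against wildtype, 0.19, became -0.0721 among members with a CPM of at least 5, and the cause was not tested. Without a change of direction, 15 of 1404 recomputed list medians, 20 of 855 values of top genes and 1 of 24 correlations also moved. By scaling, higher and lower genes became 359 and 299 for Sp6+Sp8 cKO against Sp6 cKO and 528 and 458 against wildtype with library totals without the 20 most abundant genes. All 30 recomputed log2 ratios of Sp6 and Sp8 kept their direction and size. No paired analysis was possible because there was 1 library per group, and leaving out a library leaves no comparison for its group. Depth limits low genes, since 3 counts correspond to 0.238 CPM in Sp8 cKO.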

Other observations

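The grouping of libraries used here and all tests below but that of time of day were chosen after the values had been seen, and the bounds for the time-of-day test were set before its genes were computed. With all 4 pairs past the size rule in 1 direction, 51 genes were lower in the 2 libraries with Sp6 cKO than in the 2 without, and 43 were higher. The lower genes held 8 of 55 keratin-associated protein genes and 2 of 23 members of the nail and hair keratin list, and the higher genes 4 of 8 T cell genes, with no test of enrichment. In 20 simulated sets of unchanged libraries with an assumed biological coefficient of variation of 0.25, at most 14 genes parted the libraries this way in either direction. Each gene varied independently there, with no shared shift of tissue content, sex or batch. Genes that vary together can exceed these values without any loss of Sp6, so the simulated values set no bound on the observed counts. Krt40 stood at 7.17 CPM in wildtype and 5.00 in Sp8 cKO, against 0.310 in Sp6 cKO and 1.43 in Sp6+Sp8 cKO. Krt72, Krt26, Tchhl1, Krt82, Vsig8 and Lyg2 were lower in the same libraries, with mean log2 ratios of -2.28, -2.11, -2.14, -1.74, -1.45 and -2.05. The keratin-associated protein genes Krtap5-1, Krtap5-2, Krtap5-3, Krtap5-4, Krtap12-1, Krtap17-1, Krtap24-1 and Krtap28-13 were lower too, from -2.42 for Krtap28-13 to -1.67 for Krtap17-1. The proton channel gene Otop2 was at -1.59 and Bhlha9, a transcription factor gene of limb development, at -2.48.

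Higher with Sp6 cKO were 4 Serpinb3 genes, Serpinb3a at 1.23, Serpinb3b at 1.21, Serpinb3c at 3.09 and Serpinb3d at 2.08, which encode protease inhibitors of stressed epithelium. The cornified envelope genes Sprr2b, Sprr2d, Sprr2f and Sprr2i were at 1.74, 1.42, 2.28 and 1.74. Zc3h12a, Lcn2, Alox8 and Atp12a were at 1.95, 1.71, 1.32 and 1.36. T cell genes included the gamma-delta receptor genes Trdc at 2.26 and Tcrg-C1 at 2.23, with Cd3e at 2.00, Icos at 2.01, Il2rb at 1.78 and Zap70 at 1.56. Parting the libraries by Sp8 cKO gave 14 higher and 13 lower genes, where the simulated sets at 0.25 reached 14 and 15. The single cKO libraries against wildtype and Sp6+Sp8 cKO gave 22 higher and 10 lower genes, where these sets reached 18 and 14, so the Sp6 division was not the only one past the simulated values. Stfa1, Lce3b, Skint9, Fcgr1 and Mcpt4 were among those 22. Xist had 33171, 25314, 352 and 54285 counts in wildtype, Sp6 cKO, Sp8 cKO and Sp6+Sp8 cKO. Scaled for depth, it was higher in both libraries with Sp6 cKO than in both without. It did not pass the size rule between Sp6 cKO and wildtype, so it was not among the genes parted this way. A part of sex makeup in the Sp6 division was not tested.

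Technical explanations were weighed for the nail and hair keratin genes that were lower in Sp6 cKO than in Sp8 cKO, both of batch 1. A smaller share of nail-forming tissue that lowered all members alike would lower the abundant members too. The median log2 ratio of 13 members with a mean CPM of at least 100 was -0.16 (quartiles -0.23 and -0.03), above the bound of -0.5 against. That argues against an even loss as the whole cause. The prediction was written after the values had been seen, so it is no independent test. Reads moved between near-identical keratin-associated protein copies would leave family sums alone. Sums were taken in 6 families with several measured members, each picked because a member was lower in Sp6 cKO. They had a median of -1.40 and ranged from -2.63 to -0.58. Krtap9 and Krtap19 missed the bound of -1 set against this explanation. For Krtap5, Krtap16, Krtap28 and Krtap31 the sums argue against moves among measured copies, but moves to unmeasured copies cannot be seen. In 6 other families, with 1 measured member and a median of -2.08, the sum is the gene already seen to be lower, so moved reads stay open there. Fewer hair follicles in the tissue could account for part of it, since 8 inner root sheath keratins had a median of -0.80, between the bounds of -1 for and -0.5 against. Without Krt26, Krt28 and Krt72 the median was -0.42 (quartiles -0.76 and -0.36). That is past the bound against but by less than its spread, so fewer hair follicles and loss of Sp6 stay open.

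For Per2, higher in the 3 cKO libraries than in wildtype, collection at another time of day could be a source. The median absolute log2 ratio of 8 clock genes other than Per2 was 0.65, between the bounds of 0.75 for and 0.35 against, so this stays open. Of these genes, Dbp, Per1, Per3, Nr1d2, Tef, Hlf and Ciart were higher than wildtype in each cKO library. Nr1d1 was lower in each, at -0.43, -0.42 and -0.55 in Sp6 cKO, Sp8 cKO and Sp6+Sp8 cKO. Arntl and Npas2 differed in the opposite direction to Per2, at -0.63, -0.94 and -1.24 and at -1.17, -0.91 and -1.58. More glucocorticoid signalling also stays open, with a median of 0.20 over 11 responsive genes between the bounds of 0.5 for and 0.15 against. Without Tsc22d3 and Zbtb16 it was 0.148, under the bound against but by less than its spread (quartiles -0.07 and 0.44). Within batch 1, Per2 was higher in Sp6+Sp8 cKO than in Sp6 cKO and Sp8 cKO, at 1.16 and 1.06, with Per1 at 0.13 and 0.13, Per3 at -0.20 and -0.21 and Dbp at -0.30 and -0.28. Collection time is not in the labels, batch divides the cKO libraries from wildtype, and no biological explanation was tested.

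Scrn2, a neighbour of Sp6, stood at 2.35 CPM in wildtype, 30.4 in Sp6 cKO, 3.89 in Sp8 cKO and 39.5 in Sp6+Sp8 cKO. Strain DNA carried along with the Sp6 allele could be a source. Of 47 expressed genes within 1 Mb of Sp6, Scrn2 left out, 4 passed the size rule between Sp6 cKO and Sp8 cKO, 2.78 times the share elsewhere, under the bound of 3 times. With Scrn2 kept, as the prediction was first worded, the share was 3.41 times, but Scrn2 prompted the test, so that value is no test and the explanation stays open. The other 4 were Gm11532, Gm11533, D030028A08Rik and Hoxb5. Like Scrn2, Gm11532 and Gm11533 were higher in both libraries with Sp6 cKO than in both without. Gm11532 stood at 16.9, 65.9, 14.2 and 77.9 CPM in wildtype, Sp6 cKO, Sp8 cKO and Sp6+Sp8 cKO. D030028A08Rik and Hoxb5 were not among the genes parted this way, and a biological explanation was not tested.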
